A study of Rattus norvegicus with 6 samples.

How the data were processed

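The series holds 6 RNA-seq libraries of rat H9C2 cells, 3 with small interfering RNA against PUM2 (siPUM2 1, 2 and 3) and 3 controls described as empty vector (NC 1, 2 and 3), grouped by their titles and treatment labels. Per the labels' protocols, polyadenylated RNA was captured on beads after DNase treatment, made into directional libraries in which the dUTP-marked strand was not amplified, and sequenced from both ends on an Illumina instrument. The submitters' processing notes name HISAT2, DESeq2 and the rat genome build mRatBN7.2. Their versions, the annotation and the counting program are not given in the sources used here.

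The authors deposited a table of whole-number counts per gene, not normalized, and a table of FPKM values (fragments scaled by gene length and library size, rounded to 2 decimals). Both tables name each gene by symbol with its chromosome, type and description, per the file headers. No row lacked a gene name, so 0 counts were set aside for that reason. The count table lists 19825 genes. The gene lists below were matched by symbol, current or older, through a table of RefSeq names of the assembly GRCr8, used for names only. Of 798 list entries, 705 matched by symbol, 5 by an older symbol and 13 as mitochondrial genes, 72 had no match and 3 were a further name of a gene already in the same list. The matched entries came to 716 distinct genes. No genome or transcript sequence was used here.

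The main test was edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts, with TMM factors (0.995 to 1.003), edgeR's filterByExpr and the group as the only term. The filter removed 6840 genes holding 0.0465% of the counts and left 12985. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are given as CPM with TMM scaling, as mean ± SD, and log2 fold changes are siPUM2 minus NC with the SE derived from the quasi-likelihood F statistic. The common biological coefficient of variation was 3.47%.

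Before the data were examined, 25 gene lists were fixed: collagens and matrix proteins; matrix crosslinking and turnover; TGF-beta and BMP signalling; contractile genes of myofibroblasts and smooth muscle; skeletal and embryonic muscle; cardiac muscle and natriuretic genes; proliferation; cell cycle inhibitors and DNA damage genes; apoptosis; splicing factors. The others were Pumilio family and deadenylation partners, Pumilio targets from background knowledge, the unfolded protein and integrated stress response, inflammatory genes, the interferon response, oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, cholesterol and fatty acid synthesis, ribosomal proteins, histones, and markers of fibroblasts, endothelium, macrophages and Schwann or neural cells. Each was tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Members were also counted with p-values adjusted over the list alone.

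Genes named in the text followed a rule set at the same time: Pum2, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 1 CPM, no overlap between the groups and a proper symbol, and from each list the 4 members with the lowest p. Some genes that the rule takes are not reported here. Genes without a proper symbol or of ribosomal RNA were passed over by the rule. The ribosomal RNA genes described separately and the symbol families of the closing part were chosen after the data were seen.

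Alternatives were other scaling factors, DESeq2 1.42.0, limma voom, other filters, the replicate number as a block, each library left out in turn, FPKM on a log2 scale with a pseudocount of 1 or 0.1, other thresholds, and, chosen after the data were seen, removal of each library's trend with gene length, with lengths taken from counts over FPKM, and the list tests with Pum2 taken out of its 2 lists. All pairs of libraries in a group differed by more than sampling noise (chi-square over degrees of freedom 2.08 to 3.82 within groups and 12.6 to 14.0 between them), so none was counted as a copy of another. The highest values within groups, 3.55 and 3.82, were those of siPUM2 3 against the other siPUM2 libraries.

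The gene test was tested on simulated data with the real means and depths (12888 genes), where edgeR recovered 38% of genes changed 1.15-fold, 58% at 1.25-fold, 82% at 1.5-fold and 94% at 2-fold, and 4.90% of its calls were false. Only 50 genes were changed at each fold, a far smaller share than the 28.4% called in the data. Recovery depends on that share, so these rates do not carry over to the real comparison. Of 20 simulated lists with no change, none passed any of the 3 list tests (12878 genes), while a list raised 1.1-fold gave an adjusted p of 4.05e-10 with camera, 0.0333 with the estimated correlation and 0.00403 with fry. Simulated genes varied independently of each other, which real genes do not. Splicing, for which gene-level values give no measure, and the proliferation, apoptosis and RT-qPCR assays that the labels mention were not analysed here.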

Results

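Messenger RNA was measured by RNA sequencing in H9C2 cells, a line of myoblasts derived from embryonic rat heart that the labels call cardiomyocytes. PUM2 is an RNA-binding protein of the Pumilio family, which is known to bind a short element in the 3' untranslated regions of messages and to lower their stability or translation. In 3 libraries (siPUM2) it had been knocked down by transfected small interfering RNA, and 3 control libraries (NC) came from cells that the labels describe as transfected with empty vector. By that description the control differed from the knockdown in the kind of nucleic acid transfected, but the labels do not mention a non-targeting small interfering RNA, and whether one was used is uncertain. The libraries held between 27704702 counts (siPUM2 2) and 30579237 counts (NC 3), so that 1 count was worth 0.0327 to 0.0361 CPM, the counts of a gene scaled to a common library size. Mitochondrial genes took 5.98% to 6.32% of the counts in each library. Nuclear ribosomal RNA took 0.102% of the counts in siPUM2 3 and 0.0275% to 0.0510% in the other 5 libraries. The labels do not say that the libraries of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

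The targeted gene was lower in every siPUM2 library. Pum2 (chromosome 6) was measured at 223, 228 and 225 CPM in NC 1, 2 and 3, and at 127, 126 and 120 CPM in siPUM2 1, 2 and 3. The mean fell from 225 ± 2.67 CPM to 124 ± 4.01 CPM (SD, n = 3 each), which left 55.1% of the control level. The log2 fold change was -0.86 ± 0.0279 (SE), with an adjusted p of 9.23e-19 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Pum3, a more distant Pumilio-repeat protein of the nucleolus, fell 1.16-fold, from 146 ± 6.13 to 126 ± 3.20 CPM (adjusted p = 3.69e-06, same test).

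**Figure D1:**
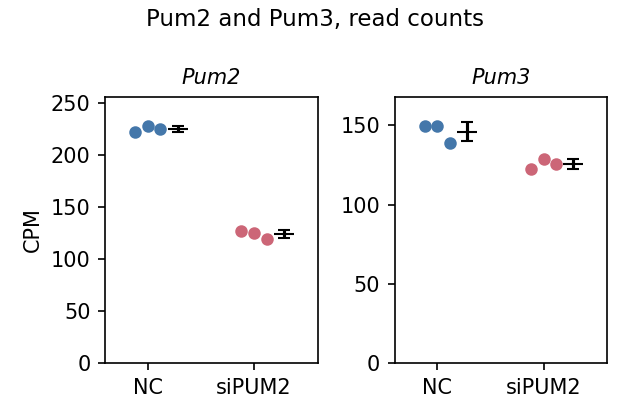
Normalised read counts (CPM, y axis from 0) of Pum2 and Pum3 in the NC and siPUM2 libraries. Each point is 1 library, and the bar beside each group is the mean with its SD (n = 3); the siPUM2 libraries sit at 120 to 127 CPM for Pum2 and the NC libraries at 223 to 228 CPM.

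The comparison of siPUM2 with NC asks which messages change when PUM2 is reduced, with genes tied to myocardial fibrosis named as the interest of the series. Of 12985 genes tested, 3692 (28.4%) changed at an adjusted p under 0.05, 1961 higher and 1731 lower in siPUM2. Most changes were small. The median called gene changed 1.15-fold and the 90th percentile was 1.38-fold, and 236 genes changed at least 1.5-fold, 146 up and 90 down. At least 2-fold changes were called for 73 genes, 43 up and 30 down. This last count fell to 32 with DESeq2, and the count at 1.5-fold to 149. With a filter at 1 CPM in at least 3 libraries the 2-fold count was 31, so many of the 2-fold calls were of low genes. The 2 groups did not overlap in 5177 of the tested genes (39.9%, where chance gives 10%).

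The genes that rose most were picked by a rule set before the data were examined. Lce1l, a late cornified envelope gene, rose 4.48-fold from 1.99 ± 0.480 to 8.99 ± 1.16 CPM (SD, n = 3; adjusted p = 4.39e-12, edgeR). Upk3b, a uroplakin, rose 2.76-fold to 20.1 ± 0.802 CPM and Art3, a member of the ADP-ribosyltransferase family, 2.28-fold to 56.1 ± 2.38 CPM. The growth factors Vegfd and Igf2 rose 2.21-fold and 2.15-fold, and Colq, the collagen-like tail of acetylcholinesterase, rose 2.16-fold. Adamtsl2, a secreted protein that binds the microfibril network, rose 3.52-fold from a low level (0.495 to 1.76 CPM). Ccdc110, Tmem59l and Gstm7, all under 3 CPM, rose 2.56-fold, 2.22-fold and 2.14-fold.

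The genes that fell most were picked by the same rule. Col6a3, a chain of collagen VI, fell 2.34-fold from a low level, 1.66 ± 0.236 to 0.707 ± 0.473 CPM, and 3.75-fold without siPUM2 1, whose 35 counts stood above the 10 and 15 of the other siPUM2 libraries. Mybph, a myosin-binding protein of skeletal muscle, fell 2.32-fold (6.74 ± 1.09 to 2.90 ± 0.649 CPM; adjusted p = 4.09e-07, edgeR). Slc7a11, the cystine importer, fell 2.25-fold and Myog, the myogenic transcription factor myogenin, fell 2.18-fold. The remaining genes of this group were Areg (2.11-fold lower), Draxin (2.08-fold), Cfap299 (2.0-fold), Cox6a2 (1.96-fold), Hist1h2ail1 (1.91-fold) and Slpi (1.90-fold). The call for Areg was lost without NC 1 (adjusted p = 0.0525). On log2(FPKM + 1) without a filter, 12 of the genes that the naming rule takes lost their calls. Among them were Col6a3 (adjusted p = 0.0780), Areg (0.109) and Cox6a2 (0.0583). The others were Flt1, S100a4, Ddr2, Irf7, ND5, ND4, COX2, Btg2 and Gadd45a. Lce1l, Gstm7 and Hist1h2ail1 belong to families of near-identical genes whose reads the counting could split, so their values are uncertain.

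One rise larger than all of these rested on a single library. LOC120099695, an 18S ribosomal RNA gene, had 6712 counts in siPUM2 3 and 25 to 121 counts in the other 5 libraries. Its log2 fold change of 5.08 (adjusted p = 0.000506, edgeR) turned to -1.32 without siPUM2 3, and it was the only one of the 3692 called genes whose direction turned when that library was left out. The 45S precursor Rn45s was also highest in siPUM2 3, at 17913 counts against 6431 to 12822 in the other libraries. Without siPUM2 3 its log2 fold change went from 0.15 (not called) to -0.43 (adjusted p = 1.57e-06), that of Rn28s from 0.54 (not called) to -0.29 (0.0226) and that of the 18S gene LOC120102105 from 0.04 (not called) to -0.49 (6.24e-05). The 28S gene LOC120093067 (1.54, adjusted p = 0.00872) lost its call (0.41, adjusted p = 0.340). The libraries were made from captured polyadenylated RNA, so these reads are ribosomal RNA that the capture left. Their share also differed within NC, from 0.0354% in NC 1 to 0.0510% in NC 3. None of these changes is therefore a measure of the level of ribosomal RNA in the cells. Without siPUM2 3, 3538 genes were called, 1798 higher and 1740 lower.

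**Figure D2:**
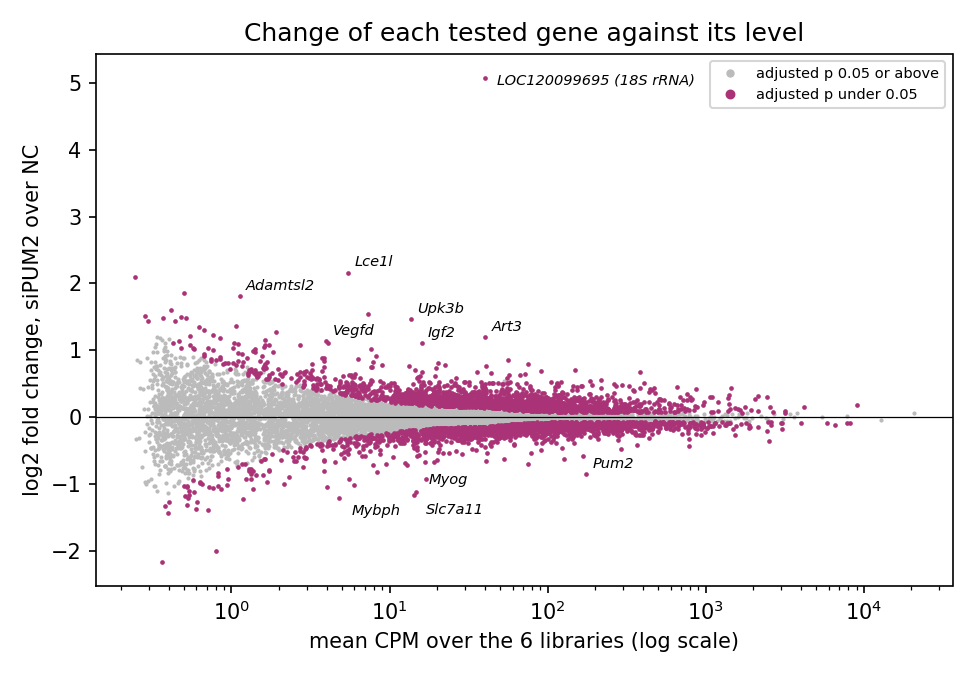
Log2 fold change of siPUM2 over NC (y axis) against mean CPM over the 6 libraries (x axis, log scale) for the 12985 genes tested. Each point is a gene, coloured where the adjusted p was under 0.05 (3692 genes); Pum2, a few of the genes that changed most and the 18S ribosomal RNA gene driven by siPUM2 3 are named.

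The gene lists that follow were fixed before the data were examined. From each list, up to 4 members with the lowest p were named by rule, and any further member is an example chosen after its values were seen. Of the 25 lists tested with camera at a preset correlation, 6 passed an adjusted p of 0.05, and 0 passed with a correlation estimated from the 6 libraries, where 3 had an unadjusted p under 0.05. Fry, which compares a list with no other genes, passed these 6 and 8 more. Higher by fry were cardiac genes (adjusted p = 0.00707), fibroblast markers (0.00385), endothelial markers (0.0289), glycolysis and hypoxia (0.0287) and matrix turnover (0.0287). Lower were collagens and matrix proteins (0.0287), the Pumilio family with its partners (0.00573) and Pumilio targets (0.00598). The last 2 lists hold Pum2 itself and did not pass fry without it (0.0644 and 0.293).

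Contractile genes of smooth muscle and myofibroblasts rose together. Of 20 measured members 14 rose, 2 fell and 4 did not pass (15 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.24. Camera gave an adjusted p of 7.98e-11 for this list, and the adjusted p = 0.174 with an estimated correlation. Lmod1, an actin-filament nucleator of smooth muscle, rose 1.62-fold from 69.1 ± 3.60 to 112 ± 4.02 CPM (SD, n = 3; adjusted p = 1.83e-14, edgeR). Myocd, the coactivator of serum response factor that drives smooth muscle genes, rose 1.57-fold from 55.7 ± 1.42 to 87.5 ± 3.19 CPM. The smooth muscle myosin heavy chain Myh11 (log2 fold change 0.70), Tpm2 (0.43) and Myl9 (0.29) rose, as did the myofibroblast markers Acta2 (0.18) and Tagln (0.27). Srf itself (-0.13) and Tpm4 (-0.10) fell.

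Genes of skeletal and cardiac muscle went both ways. Of 28 skeletal and embryonic muscle genes 8 rose, 7 fell and 13 did not pass, with the same counts adjusted over the list alone. Myog (adjusted p = 1.86e-09, edgeR), the fast myosin light chain Mylpf (1.90-fold lower; 22.4 ± 4.5 to 11.8 ± 0.852 CPM), and embryonic myosin Myh3 (log2 fold change -0.93; call lost without NC 1, adjusted p = 0.106) fell, whereas Tnnc2 rose 1.41-fold, Mef2c 1.21-fold and Myl4 by a log2 fold change of 0.41. The list did not pass camera (adjusted p = 0.779), and its median (0.03) and test were positive where its mean (-0.15) was negative. Of 16 cardiac genes 6 rose, 2 fell and 8 did not pass (6 and 3 adjusted over the list alone). Cardiac troponins Tnnt2 (1.59-fold, 298 ± 28.8 to 474 ± 32.4 CPM) and Tnnc1 (1.42-fold, 339 ± 23.9 to 480 ± 27.2 CPM) rose, as did Ankrd1 (1.24-fold) and the calcium-pump regulator Pln (log2 fold change 0.83), while the gap-junction gene Gja1 fell 1.63-fold from 93.6 ± 3.59 to 57.6 ± 0.828 CPM (adjusted p = 1.50e-14, edgeR). This list did not pass either (adjusted p = 0.283); its median was negative (-0.08), and its mean (0.02) and test were positive.

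**Figure D3:**
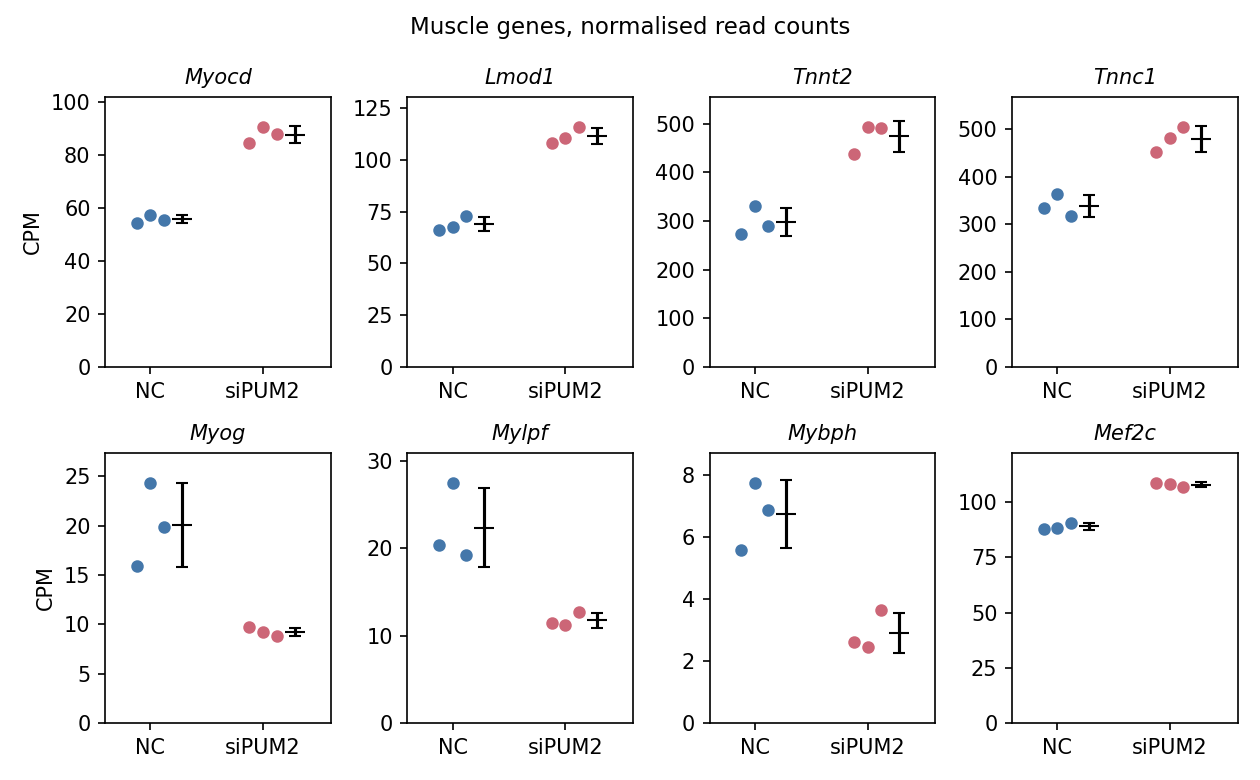
Normalised read counts (CPM, y axes from 0) of 8 muscle genes in the NC and siPUM2 libraries, with each point a library and each bar a mean with its SD (n = 3). Myocd, Lmod1, Tnnt2, Tnnc1 and Mef2c were higher in every siPUM2 library than in every NC library, and Myog, Mylpf and Mybph were lower.

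Genes of the extracellular matrix, which build scar tissue in fibrosis, moved in both directions. Of 31 collagens and matrix proteins 8 rose, 13 fell and 10 did not pass, and the counts were the same adjusted over the list alone. Periostin (Postn), a matricellular protein of activated fibroblasts, fell 1.55-fold from 64.1 ± 0.591 to 41.4 ± 2.25 CPM (SD, n = 3; adjusted p = 2.58e-11, edgeR), tenascin C (Tnc) fell by a log2 fold change of -0.83, and Col16a1 fell 1.24-fold. Mfap5 and Nid2, of microfibrils and basement membranes, each rose 1.40-fold. Of the collagen I chains, Col1a1 was at a log2 fold change of -0.08 (called, but not without NC 2, adjusted p = 0.0716, or without siPUM2 2, 0.0844) and Col1a2 at 0.02 (not called). The list did not pass camera (adjusted p = 0.238), although its mean log2 CPM was lower in every siPUM2 library than in every NC library, by 2.83 times the widest range within a group (difference -0.10 ± 0.0144, SE). Its median log2 fold change of -0.05 did not stand out from genes of like expression. Of 10000 random lists matched on mean CPM, 1624 had a median as low. Of 31 genes of matrix crosslinking and turnover 11 rose and 7 fell (12 and 8 adjusted over the list alone), among them the proteases Adamts1 (1.34-fold higher), Mmp11 (1.44-fold higher) and Plat (1.25-fold higher) and the lysyl oxidase-like enzyme Loxl3 (1.20-fold lower); the list did not pass (adjusted p = 0.287).

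Ligands and targets of TGF-beta signalling, a profibrotic pathway, also split. Of 37 members 8 rose, 13 fell and 16 did not pass (8 and 14 adjusted over the list alone), and camera gave an adjusted p of 0.378. Tgfb3 rose 1.34-fold from 744 ± 30.6 to 998 ± 24.7 CPM (adjusted p = 2.19e-12, edgeR) and Tgfb2 rose 1.23-fold, while Tgfb1 fell by a log2 fold change of -0.15. Tgfbi, a matrix protein induced by TGF-beta, fell 1.51-fold from 201 ± 3.89 to 134 ± 4.98 CPM and Ltbp4 fell 1.22-fold. The BMP-responsive genes Id1 (log2 fold change -0.29), Id2 (-0.52), Id3 (-0.25) and Smad6 (-0.58) fell. Connective tissue growth factor (Ccn2) was not called, at 0.05. Of 8 fibroblast markers 4 rose and 3 fell, with the same counts adjusted over the list alone, led by Thy1 (1.24-fold higher) and S100a4 (1.14-fold lower). That list did not pass (adjusted p = 0.524), and its median (-0.01) was negative where its mean (0.03) and test were positive.

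Most genes of proliferation were lower in siPUM2, by small amounts. Of 53 genes acting from S phase to mitosis 32 fell, 1 rose and 20 did not pass (34 and 2 adjusted over the list alone), with a median log2 fold change of -0.13. Camera gave an adjusted p of 1.42e-10, and the adjusted p = 0.174 with an estimated correlation. The centromere histone Cenpa fell 1.23-fold (101 ± 2.66 to 81.7 ± 2.37 CPM; adjusted p = 2.87e-08, edgeR), the replicative helicase subunit Mcm6 1.19-fold and the G1 kinase Cdk4 1.17-fold. Survivin (Birc5) had the lowest log2 fold change of the list, -0.35, and the proliferation marker Mki67 had -0.19. The exception was the D-type cyclin Ccnd3, which rose 1.20-fold (458 ± 6.74 to 551 ± 5.59 CPM).

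Cell-cycle inhibitors and apoptosis genes did not move as groups. Of 21 cell cycle inhibitors and DNA damage genes 2 rose and 5 fell, with the same counts adjusted over the list alone; Cdkn1a, encoding the inhibitor p21, rose 1.18-fold, and Btg2 (1.11-fold) and Gadd45a (1.20-fold) fell. The list did not pass (camera adjusted p = 0.524). Of 34 apoptosis genes 5 rose and 5 fell (6 and 5 adjusted over the list alone). The antiapoptotic gene Bcl2l1 rose 1.10-fold from 109 ± 0.809 to 120 ± 1.24 CPM (SD, n = 3; adjusted p = 0.000261, edgeR). The proapoptotic gene Bid rose 1.12-fold and the death receptor gene Fas by a log2 fold change of 0.30. Bok (1.14-fold) and Pmaip1 (log2 fold change -0.60), also proapoptotic, fell. The call for Pmaip1 was lost without NC 2 (adjusted p = 0.0631, edgeR). The apoptosis list did not pass (adjusted p = 0.954), and its median and mean (both -0.01) were negative where its test was positive.

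Splicing factors fell as a group. Of 55 members 31 fell, 2 rose and 22 did not pass (33 and 3 adjusted over the list alone), with a median log2 fold change of -0.09; camera gave an adjusted p of 3.70e-08, and the adjusted p = 0.186 with an estimated correlation. The U1 protein gene Snrpa fell 1.20-fold (105 ± 1.36 to 87.3 ± 2.06 CPM; adjusted p = 7.36e-08, edgeR), and Srsf1 and Hnrnpa3 each fell 1.16-fold. The members that rose were Mbnl1 (1.20-fold, 108 ± 2.70 to 130 ± 4.63 CPM) and Mbnl2 (log2 fold change 0.24), the muscleblind regulators of splicing during muscle differentiation. Splicing itself was not analysed here.

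Cytosolic ribosomal protein genes fell slightly. Of 48 members 31 fell, none rose and 17 did not pass (35 fell adjusted over the list alone), with a median log2 fold change of -0.09. Camera gave an adjusted p of 1.38e-13, and the adjusted p = 0.559 with an estimated correlation. Rpl10 fell 1.13-fold and Rps2 and Rps6 each 1.12-fold. Among 30 Pumilio family members and deadenylation partners 3 rose and 6 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.258). Besides Pum2 and Pum3, the poly(A)-specific ribonuclease Parn fell 1.22-fold and Pabpc4 1.12-fold. Of 10 Pumilio targets named from background knowledge 1 rose and 1, Pum2 itself, fell, with the same counts adjusted over the list alone. Eif4e (log2 fold change -0.05) and Mapk14 (-0.04) were not called, nor were 6 others, and the list gave an adjusted p of 0.494. Without Pum2 the other 9 had a median of -0.001 and a mean of 0.02, and the adjusted p was 0.954 with the opposite direction.

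Among genes of the integrated stress response and the unfolded protein response, more fell than rose. Of 35 members 15 fell, 2 rose and 18 did not pass (18 and 2 adjusted over the list alone), with a median log2 fold change of -0.09. The list passed camera with an adjusted p of 2.94e-06, and the adjusted p = 0.428 with an estimated correlation. The lowest log2 fold changes of the list were those of Slc7a11, Trib3, Atf3 and Chac1. Slc7a11 fell from 19.7 ± 0.910 to 8.75 ± 2.53 CPM (SD, n = 3; adjusted p = 2.12e-09, edgeR), Trib3 had a log2 fold change of -1.02 (-1.61 without siPUM2 3), Atf3 of -0.90 and Chac1 of -0.46. The serine synthesis gene Psat1 and the chaperone Pdia4 each fell 1.20-fold, and Vldlr rose 1.20-fold. The mean log2 CPM of the list was 6.11, 6.13 and 6.26 in siPUM2 1, 2 and 3, so that siPUM2 3 stood nearest to the NC libraries (6.32 to 6.38).

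Some mitochondrially encoded messages fell, and nuclear genes of oxidative phosphorylation did not move as a group. Of 13 mitochondrial messages 7 fell and none rose, with the same counts adjusted over the list alone. ND1 fell 1.15-fold (adjusted p = 1.66e-07, edgeR), ND5 1.19-fold, ND4 1.13-fold and COX2 1.09-fold. Camera gave an adjusted p of 0.000846 for this list, and the adjusted p = 0.428 with an estimated correlation. Its median log2 fold change of -0.08 did not stand out from genes of like expression, since 805 of 10000 random lists matched on mean CPM had a median as low. Of 40 nuclear genes of oxidative phosphorylation 6 rose and 8 fell (6 and 9 adjusted over the list alone), led by Cox7c (1.17-fold higher) and Atp5f1b (1.10-fold lower). That list did not pass (camera adjusted p = 0.872), with a negative direction where the median (0.004) and the mean (0.0002) were positive.

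Metabolic lists split as well. Of 27 genes of glycolysis and hypoxia 7 rose and 3 fell, with the same counts adjusted over the list alone. The hypoxia-induced genes Adm (1.59-fold, 27.5 ± 2.09 to 43.8 ± 2.14 CPM) and Bnip3 (1.34-fold) and the muscle phosphofructokinase Pfkm (1.36-fold) rose, and the glucose transporter Slc2a3 fell 1.41-fold (adjusted p = 8.94e-13, edgeR). The list did not pass (adjusted p = 0.457), and its median (-0.002) was negative where its mean (0.06) and test were positive. Of 30 genes of cholesterol and fatty acid synthesis 10 rose and 9 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.954). The desaturase gene Fads2 fell 1.15-fold from 424 ± 5.54 to 367 ± 9.48 CPM (adjusted p = 3.95e-07, edgeR), whereas Mvd rose 1.16-fold and Acly 1.15-fold.

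Innate immune genes showed no group change. Of 25 inflammatory genes 4 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.779). Tnfaip6 rose 1.49-fold from 12.1 ± 1.23 to 18 ± 1.38 CPM, Icam1 1.17-fold, Nfkb2 1.15-fold and the cytokine receptor Il6st 1.15-fold, and Tnfaip3 had a log2 fold change of -0.56. Of 28 interferon-response genes 5 rose and 2 fell (5 and 3 adjusted over the list alone). Isg20 (1.40-fold), Irf3 (1.31-fold) and B2m (1.16-fold) rose. The rise of Irf7 (1.29-fold) lost its call without NC 1 (adjusted p = 0.0778), without NC 2 (0.0743), with DESeq2 (0.163) and on filtered FPKM (0.0682 and 0.0683), and was 1.47-fold without NC 3. Camera gave the interferon list an adjusted p of 0.283, and 0.0447 without NC 3.

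Of the matched markers of other cell types, 4 of 11 endothelial, 4 of 8 macrophage and 5 of 9 Schwann cell or neural genes passed the count filter. Of the 4 endothelial markers Eng and Flt1 each rose 1.08-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.457), and either call was lost in some of the runs that left out 1 library. The adjusted p of Eng was 0.0524 without NC 2 and 0.0556 without siPUM2 1; that of Flt1 was 0.0779 without NC 1, 0.0520 without NC 3 and 0.0605 without siPUM2 1, and also 0.104 to 0.135 on FPKM and 0.127 with the trend with gene length removed. None of the 4 macrophage markers passed, over all genes or adjusted over the list alone (adjusted p = 0.978); Cd14 was the most abundant, at 36.0 ± 0.193 CPM in NC and 38.8 ± 1.02 CPM in siPUM2. It was called only on FPKM with a filter (log2 fold change 0.10, adjusted p = 0.0396 with either pseudocount, against 0.0528 to 0.249 in the other alternatives). Of the 5 Schwann cell and neural markers Tubb3 alone rose, 2.47-fold from 0.380 ± 0.102 to 0.951 ± 0.159 CPM, with the same count adjusted over the list alone. DESeq2 gave Tubb3 no adjusted p. That list gave an adjusted p of 0.978, with a negative median (-0.10) and mean (-0.01) and a positive test. Nes, at 0.05, was called only without NC 2 (log2 fold change 0.10, adjusted p = 0.0383, against 0.0737 to 0.933 in the other alternatives). Of 5 histone genes, most of whose messages lack a poly(A) tail, H1f2 fell 1.65-fold from 16.0 ± 1.57 to 9.72 ± 0.733 CPM (adjusted p = 1.31e-07, edgeR) and the other 4 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.494).

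**Figure D4:**
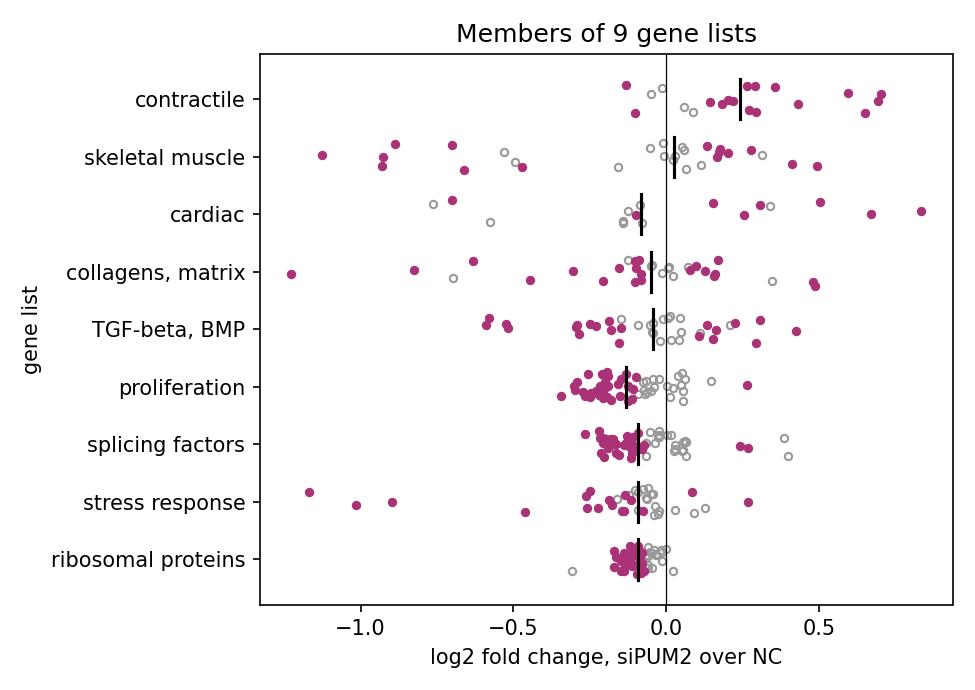
Log2 fold changes of siPUM2 over NC (x axis) for the measured members of 9 gene lists (y axis), 1 point per gene, with filled points for an adjusted p under 0.05 and a bar at each list's median. The contractile list lies mostly to the right of 0 (median 0.24), the proliferation, splicing, stress and ribosomal lists mostly to the left (medians -0.13, -0.09, -0.09 and -0.09), and the muscle, matrix and TGF-beta lists spread to both sides.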

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

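All alternatives were planned except the removal of the length trend and of Pum2 from its lists, which were chosen after the results were seen. Pum2 stayed lower in every alternative, at log2 fold changes of -0.88 to -0.84 when 1 library was left out. The count of called genes (3692, with 1961 higher and 1731 lower) ranged from 3004 to 3538 without 1 library (1603 to 1798 higher, 1395 to 1740 lower), which leaves fewer samples, and was 3091 with DESeq2, 3732 with limma voom, 3685 to 3779 with other scaling factors (48.2% higher with upper-quartile factors, against 53.1%), 3668 without a filter and 3844 with the length trend removed. It fell to 2246 (1160 higher, 1086 lower) on log2(FPKM + 1) without a filter. On the same scale with a filter at a mean FPKM of 1 it was 3062, so the fall came with leaving out the filter. By construction, stricter thresholds gave fewer calls: 236 (146 and 90) at 1.5-fold, 73 (43 and 30) at 2-fold, and 2486 (1360 and 1126) at an adjusted p under 0.01. The 1.5-fold count was 149 with DESeq2 and 39 to 96 with FPKM; the 2-fold count was 32 with DESeq2, 31 with a filter at 1 CPM and 3 to 15 with FPKM. The pseudocount shrinks folds of low genes. The filter at 1 CPM only takes out low genes and still gave 3693 calls, so its lower 2-fold count reflects the loss of low genes. The other causes were not tested.

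Of the gene lists, 6 passed camera, 6 to 7 without 1 library, 0 with an estimated correlation and 14 with fry, which tests another question. Lists far from the threshold changed direction, for causes not tested. They were cholesterol synthesis (adjusted p = 0.848 to 0.987 without 1 library, turned without NC 2 and siPUM2 2), macrophage markers (0.654 to 0.968, turned without NC 2, NC 3 and siPUM2 2, with fry at 0.975 and with the length trend removed at 0.998), oxidative phosphorylation (0.434 to 0.968, turned without NC 1 and siPUM2 1 and with the length trend removed at 0.761) and neural markers (0.824 to 0.981, turned without NC 1 and siPUM2 3 and without a filter at 0.945). Pumilio targets turned without Pum2 (0.954), the member that set their direction. For 117 named genes the alternatives gave 2064 tested values, of which 2029 kept direction and side of the threshold, 26 lost and 3 gained a call, and 6 turned, none of them among the 103 called genes. Those were Egfl7 (log2 fold change -0.066 to 0.039 without 1 library), Vwf (-0.044 to 0.075) and Csf1r (-0.68 to 0.61, and 0.36 with voom).

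With the replicate number as a block, Pum2 was at -0.86, 3731 genes and 6 lists were called. The numbers mark little else: the deviations of NC and siPUM2 libraries with the same number correlated at 0.03, 0.02 and 0.003 across genes, and NC 3 correlated best with siPUM2 2 (0.04), so the numbers were not taken to pair the samples. A correction for GC content, that correction with the block, and all tests of Pumilio elements in 3' untranslated regions were planned and not run, since no genome or transcript sequence was used here. Depth limits low genes: 1 count was worth 0.0327 to 0.0361 CPM.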

Other observations

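The families of gene symbols, the counts in other splits of the libraries, the scaling test, the removal of the trend with gene length and the comparison of list means between libraries (except for ribosomal proteins) were chosen after the results were seen. Genes were grouped into 193 families by the stem of their symbol, with exceptions made after the values by stem were seen. Integrin alpha chains and initiation factors were grouped by what the gene encodes, the latter without binding proteins and kinases. Rab GTPases were kept by stem, with symbols of Rab effectors left out. Tested with camera as above, 16 families passed (5 higher, 11 lower), and 0 passed with an estimated correlation, where 12 had an unadjusted p under 0.05. Integrin alpha chains, the receptors that tie cells to the matrix, had a median log2 fold change of 0.15. Of 11 chains 7 rose and 1 fell (adjusted p = 0.0110; adjusted p = 0.746 with an estimated correlation). Itga8, a receptor chain of smooth muscle and myofibroblasts, rose 1.72-fold, the collagen and laminin receptor chain Itga1 1.69-fold, Itga10 1.44-fold and the muscle laminin receptor chain Itga7 1.35-fold. Itga11, a collagen receptor chain of fibroblasts, fell 1.54-fold (adjusted p = 6.71e-14, edgeR), while the fibronectin receptor chain Itga5 was not called (log2 fold change -0.003). Genes with the symbol stem Akap, named after A-kinase anchoring proteins, had 8 of 14 members higher and none lower (camera adjusted p = 0.0108, and 0.746 with an estimated correlation). Akap8l was at 1.70-fold, Akap6 at 1.42-fold and Akap12 at 1.38-fold. They were grouped by symbol, so binding of protein kinase A by each member is not implied.

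Some families of translation and ribosome assembly were lower. Of 45 genes of translation initiation factors 22 fell and 3 rose (adjusted p = 1.43e-05), of 8 nucleolar Nop genes 7 fell and none rose (adjusted p = 0.00519), and of 10 Utp genes of the small-subunit processome 6 fell and none rose (adjusted p = 0.0219); with an estimated correlation the adjusted p was 0.746 for each of these 3. Elongation factors (Eef, adjusted p = 0.603), mitochondrial ribosomal proteins (Mrpl 0.0698, Mrps 0.267) and the Nol (0.130), Rrp (0.202) and Exosc (0.662) families did not pass. Nucleoporins (Nup) had 11 of 21 members lower and none higher (adjusted p = 0.00519; adjusted p = 0.746 with an estimated correlation). Rab GTPases of vesicle traffic went the other way, with 16 of 46 higher and 3 lower (adjusted p = 0.00617; adjusted p = 0.746 with an estimated correlation).

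The contractile list was higher while the proliferation and splicing factor lists were lower. Gene length is argued against as the cause, since each list kept at least 97.1% of its median once each library's trend with length was removed. So is a trend with expression level, since 0 of 10000 random lists matched on expression had a median as far out for any of the 3 lists. Typical medians of matched lists were -0.03 for contractile, -0.002 for proliferation and -0.009 for splicing genes. Matched genes were drawn independently, so these lists spread less than lists whose genes move together. Scaling moves all genes of a library alike, so it could not raise the contractile list and lower the others. Its check, in which other factors moved the median of all genes by at most 0.0102, adds nothing to this. For contractile and proliferation genes, the list means differed between the groups by at least 2.92 times the widest range within a group. The difference exceeded that range by more than 2 standard errors, a bound set after the results were seen. A shift between libraries not tied to the group would have to be larger than any seen within a group. It is not excluded, since these lists were picked for their difference in the same libraries, and no split of the libraries can give an exact p under 0.1. For splicing factors such a shift cannot be told apart from an effect of the knockdown: the ratio was 1.40, and the difference of -0.06 exceeded the range of 0.0460 by about 1 standard error (0.0162). Also open are an effect of lower PUM2 itself, an effect of the small interfering RNA beyond PUM2 and a control described as empty vector, which the design confounds with the knockdown, and cultures at different density, which the labels do not record.

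Ribosomal protein genes were lower by a median log2 fold change of -0.09. A trend with expression level is argued against as the whole cause, since the typical median of lists matched on expression was -0.02. Of these matched lists, 2 of 10000 had a median as low. That count overstates how rare the fall was, since matched genes were drawn independently and ribosomal protein genes move together (estimated correlation 0.70). A shift between libraries not tied to the group cannot be told apart from an effect of the knockdown: the groups' list means did not overlap and differed by 1.44 times the widest range within a group. That ratio passed the bound of 1 set beforehand, but the bound was too weak, because the difference of -0.09 exceeded the range of 0.0648 by about 1 standard error (0.0262); the demand that it exceed the range by more was added after the value was seen.

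The stress-response list was lower, with siPUM2 3 nearest to the controls. That 1 library decides the call at the preset correlation is argued against, since the highest camera adjusted p with any library left out was 5.88e-05. With an estimated correlation the list did not pass even with all libraries (camera adjusted p = 0.428), so the call itself rests on the preset value. A trend with expression level is argued against, since matched lists had a typical median of -0.009, and 9 of 10000 had one as low. That count overstates how rare the fall was, since matched genes were drawn independently and the genes of this list move together (estimated correlation 0.19). Gene length is argued against as well (102% of the median kept after the trend was removed). A shift between libraries not tied to the group cannot be told apart from an effect of the knockdown: the groups' list means did not overlap, but differed by only 1.22 times the widest range within a group, and the difference of -0.18 exceeded the range of 0.144 by less than 1 standard error (0.0495). A difference in medium or density between the cultures, or in transfection stress between vector and small interfering RNA, stays open.

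The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.1 can be had. The real split called 3692 genes and was the only 1 of the 10 to do so, with 0 genes in the highest other by the same edgeR test. At an unadjusted p under 0.05 the real split gave 4977 genes and the others 217 to 326. Every other split puts libraries of both groups on both sides, so the real difference widens the spread within each side. Their low counts therefore do not gauge how many of the calls are false. For gene lists, 2 of 10 splits brought as many past camera's threshold, 6 in the real split and 6 in the highest other. In the 9 other splits, each of which still carries part of the real difference, the preset correlation called proliferation 6 times, ribosomal proteins 5 times, contractile genes, splicing factors and the stress response 3 times each and mitochondrial messages 2 times. Lists that did not pass in the real split were called too: the interferon response 2 times, and histones, oxidative phosphorylation and TGF-beta signalling 1 time each. For ribosomal proteins and the stress response the lowest camera adjusted p of another split (8.10e-24 and 2.01e-07) was below that of the real split (1.38e-13 and 2.94e-06). Camera at the preset correlation thus also called lists without the real grouping.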
